A study of Mus musculus with 8 samples.

How the data were processed

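The series measured RNA from the thoracic aorta of mice that lacked Fto (Fto -/-) or carried it (Fto +/+), with 4 samples of each genotype. Fto encodes a dioxygenase that removes methyl groups from adenosine in RNA. Per the labels, all mice were male, of a mixed C57BL6J/NMRI background, kept under 12 h of light and 12 h of dark, and RNA entered the study with an integrity number above 8. Labelled RNA of each sample was hybridised with a single dye (Cy3) to 1 array of a mouse expression microarray, per the labels' protocols. The labels do not say that each sample came from a separate animal, so p-values measure the spread between these samples.

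The deposited scanner files hold intensity values per spot, made with Agilent Feature Extraction 11.0.1.1, per the file headers. The processed intensity is background-subtracted by that software and is not normalised between arrays, per the file headers. The deposited series table holds log2 values of the same arrays. In that table each probe was centred on its median over the 8 arrays, as found from the values. Its columns tracked the log2 intensity of the scanner files with slopes from 0.959 to 1.006 and correlations from 0.983 to 0.997 over the 22233 probes well above background on every array. The column medians lay between -0.0095 and 0.0048. Its scale, centring and direction were settled by this comparison, and the normalisation behind it is not given in the sources used here. All 8 arrays lay on 1 slide with 1 scan date in the headers, so neither could be fitted as a batch.

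Control spots (3671 per array) were left out, which left 59305 spots for 55681 probes. Spots that the scanner software called outliers, 126 to 189 per array, were set to missing. Spots of a probe were averaged. Each value was the log2 of the processed intensity minus the 75th percentile of its array. A probe was tested where it was well above background on at least 4 of the 8 arrays, whatever their genotype, which 25292 probes were. Of all probes, 28331 (50.9%) were named through their RefSeq accession in a gene table of assembly GRCm38.p6; 16194 carried a genomic region of build mm9 as their identifier. The files annotate the array on mm9, so no coordinates of the gene table are given. The tested probes held 17003 named probes for 13053 genes and 8289 unnamed probes.

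Genotypes were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, as Fto -/- minus Fto +/+, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. For a gene with several tested probes, the probe of highest mean over all 8 arrays stood for the gene. Of 290 genes with a probe past the threshold, 103 had over 1 tested probe, of which 17 had every tested probe past it, and 0 had probes past it in opposite directions. Where a probe was not well above background on any array of 1 genotype, the difference is a bound: the mean of the brighter genotype was set against the mean, over the dimmer arrays, of the higher of the probe's own level and the lowest level among probes well above background on that array. Fto itself was compared by an exact two-sided permutation test.

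Gene lists and the rule for named genes were fixed before the data were examined. The lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with at least 5 measured genes, and adjusted over the 27 lists so tested. The set tests were repeated with an estimated correlation and with fry, whose directional p asks only whether a list's genes moved, on balance, one way, and whose mixed p asks whether they changed in either direction. The level of a list in an array is the mean of its genes after each gene was centred over the 8 arrays. The limma p-values of a list's genes were also adjusted over that list alone. This is a laxer threshold and was not corrected across lists. A gene said to rise or fall only there missed the threshold over all tested probes with the probe that stood for it. The genes named are Fto, the 12 genes with the largest fitted increase and the 12 with the largest fitted decrease among named genes past the threshold with no overlap between genotypes (clone and lincRNA names left out). To these come the members of each list past the threshold, at most 4 of smallest p, or else the 2 of smallest p of a list that is described, and markers of other tissues. Some genes that this rule takes are not reported here. Which lists are described in more detail was decided after the values were seen. The genes named outside the rule were also chosen after their values were seen: Acta2 and Myh11 as markers of the vessel itself, the members that passed only over a list alone (Igf2bp2, Tbxa2r, Gucy1a1, Des, Fn1, Col6a3, Postn, Cxcl9, Thrsp, Acacb, Ghr, Socs2, Igf1r, Igfbp3 and H19), and all genes first named after the report.

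The fit was tested on simulated data with 25269 probes drawn at the real means and spreads, each independently of the others. Probes that vary together, as within the gene lists here, were not simulated, so the rates below may not hold for the real arrays. For this comparison 50 changed probes of each size were planted: 14% of those changed by 0.5 on the log2 scale were recovered, 64% at 1, 88% at 2 and 96% at 3, with 4 false calls among 135. Alternatives covered the background correction, the normalisation, the series table, the filter on dim probes, the outlier spots, the variance model, array weights, blocks for replicate number and slide row, and leaving out each array. The array number limits the precision. The percentage of probes well above background ran from 44.5% to 47.77% per array.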

Results

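Gene expression in thoracic aorta was compared between 4 Fto -/- and 4 Fto +/+ samples to ask how loss of Fto alters expression in the vessel. Each sample was read on its own array. The 75th percentile of processed intensity ran from 294.9 to 415.6 between arrays. The share of probes well above background was higher in the Fto -/- arrays, at 46.29% ± 1 (SD, n = 4) against 44.8% ± 0.324 (SD, n = 4), with an exact two-sided permutation p of 0.0286, the smallest this design can give. The 25th percentile of intensity was lower in the Fto -/- arrays, at 7.793 ± 0.634 against 9.516 ± 0.665 (SD, n = 4 each; exact two-sided permutation p = 0.0286).

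Fto was lower in every Fto -/- sample than in every Fto +/+ sample. Its single probe (NM_011936) fell 8.47-fold, a log2 difference of -3.08 ± 0.15 (SE). The level relative to the 75th percentile was -2.51 ± 0.24 (SD, n = 4) in Fto -/- and 0.57 ± 0.21 (SD, n = 4) in Fto +/+ samples. The exact two-sided permutation p was 0.0286, the smallest possible, and the limma adjusted p was 0.000403. The free-text description of every sample names the opposite genotype of its title and genotype fields; the groups follow title and genotype, and the Fto level followed them. The probe remained well above background on all 4 Fto -/- arrays, at intensities of 49.2 to 70.1, and where it lies relative to the deleted part is not given in the sources used here. With slide row as a block the log2 difference was -3.18 (adjusted p = 0.00377), and within the rows it was -3.02 and -3.33 (adjusted p 0.154 and 0.32), each from 1 array against 3. Without the 4 arrays on which Rag1 was well above background, also chosen after seeing the data, it was -2.66 (adjusted p = 0.129). With normexp background correction, an alternative chosen after seeing the data, it was -1.96 (adjusted p = 3.64e-05).

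All samples were labelled male. Both Xist probes, which read the RNA that coats the inactive X chromosome, were well above background on all 8 arrays, at intensities of 302 to 1260. Probes of the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Zfy1 were well above background on 0 of the 8 arrays. Of the Uty probes, 1 was well above background on 1 array, Fto +/+ replicate 3, and the other on none.

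Loss of Fto was accompanied by higher signal of 213 probes (136 named genes) and lower signal of 206 probes (154 named genes), 1.66% of the 25292 tested. Ptgds, which encodes the lipocalin-type prostaglandin D synthase, rose 4.54-fold (log2 difference 2.18 ± 0.24 SE, adjusted p = 0.00843). Its level was -0.79 ± 0.37 (SD, n = 4) in Fto -/- and -2.97 ± 0.4 (SD, n = 4) in Fto +/+ samples, of which 3 measured it above background. Mttp, which loads lipid onto apolipoprotein B particles, rose 4.32-fold (2.11 ± 0.21 SE, adjusted p = 0.00761), also measured in 3 of the Fto +/+ samples. The sizes depend on the processing: over all settings the lowest log2 difference was 1.23 for Ptgds and 1.25 for Mttp. The lectin receptor gene Cd209d rose 4.21-fold, the splicing regulator gene Rbfox1 4.02-fold, the sodium channel subunit gene Scn2b 3.52-fold and the pterin dehydratase gene Pcbd1 3.31-fold, with adjusted p from 0.00373 to 0.0296. A second Rbfox1 probe gave a log2 difference of 2.08. The other genes with the largest increases were not well above background on any Fto +/+ array. The water channel gene Aqp5 was at least 2.03-fold higher, the lipid transporter gene Mfsd2a at least 2.9-fold, the acute-phase protein gene Orm3 at least 2.73-fold, Begain at least 2.02-fold, Kbtbd12 at least 1.8-fold and Psrc1 at least 1.29-fold (adjusted p from 0.00834 to 0.0444). These bounds hold for the main processing. In other settings the fitted log2 differences were as low as 0.79, 0.96, 0.79, 0.67, 0.77 and 0.43, in the same order. All but that of Psrc1 lie under the bound.

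Cstad fell 6.55-fold (-2.71 ± 0.44 SE, adjusted p = 0.028). Bcan, which encodes the proteoglycan brevican, fell 4.55-fold, Lrtm2 4.37-fold, Phyhd1, of the same oxygenase superfamily as Fto, 3.42-fold, and Efcab9 3.39-fold. Kcnip4, which encodes a potassium channel-interacting protein, fell 2.59-fold, the homeobox gene Gsc 2.42-fold, the inter-alpha-trypsin inhibitor gene Itih4 2.36-fold and the histone gene H2bc4 2.34-fold. Adjusted p values of these 8 genes lay between 0.00761 and 0.0444. The weakest log2 differences over all settings were -1.12 for Bcan, -1.3 for Lrtm2, -1.13 for Phyhd1, -0.98 for Efcab9 and -0.62 for Gsc. A second Itih4 probe gave -1.42 and passed, and a second Kcnip4 probe gave -1 and did not. H2bc4 belongs to a family of near-identical histone genes, so its probe can read other members. Asb5, Trim6 and Rnf39 were not well above background on any Fto -/- array and were at least 2.58-fold, 1.84-fold and 2.18-fold lower (adjusted p 0.0248, 0.0131 and 0.0221). These bounds too hold for the main processing. In other settings the fitted log2 differences were as weak as -0.7, -0.58 and -0.42, each under its bound.

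**Figure D1:**
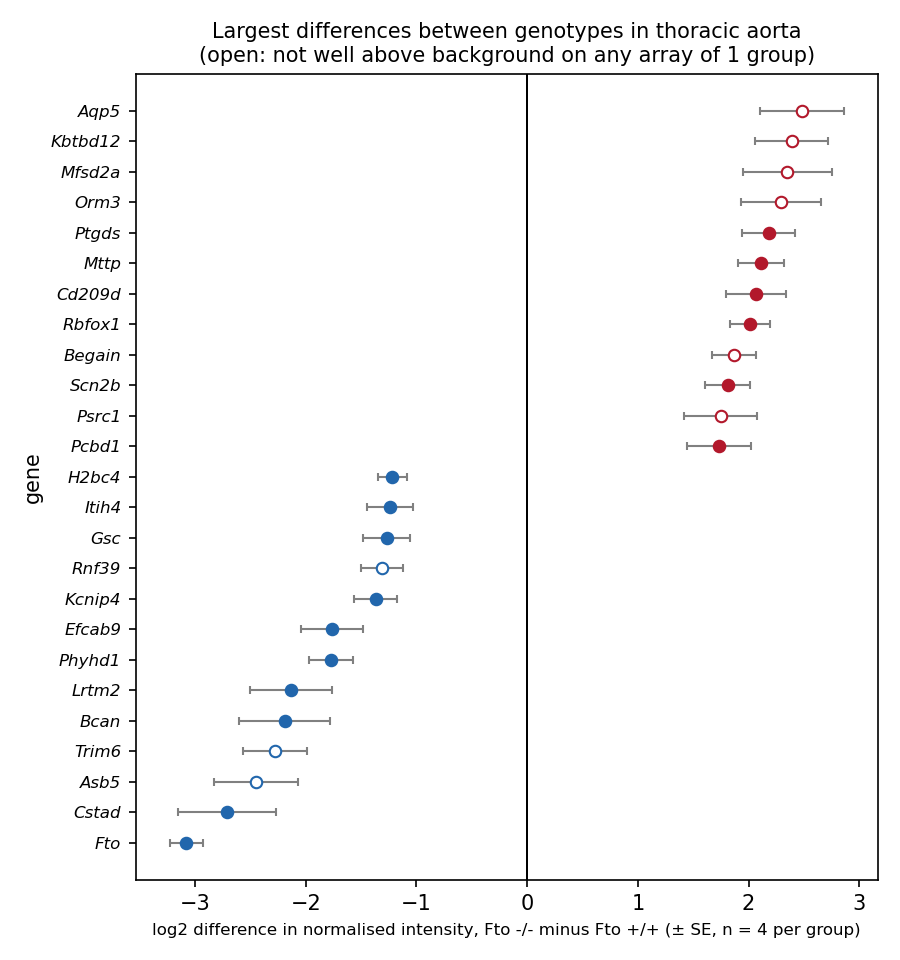
Log2 difference in normalised intensity (x axis) of Fto and of the 12 genes with the largest fitted increase and the 12 with the largest fitted decrease (y axis), with SE from the limma fit and n = 4 per genotype. Open points mark genes not well above background on any array of 1 genotype, for which only a bound holds; Fto lies at -3.08 and Ptgds at 2.18.

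Among the probes past the threshold, 92 rose and 44 fell by at least 2-fold, with dim probes taken at their bound (106 and 48 by fitted difference), and all 419 had no overlap between genotypes, as had 12.1% of tested probes against 2.86% by chance. Of the 24 genes taken by fitted difference, 10 kept their call whichever 1 of the 8 arrays was left out: Kbtbd12, Ptgds, Mttp, Cd209d, Rbfox1, Begain, Scn2b, Trim6, Phyhd1 and H2bc4. Kcnip4 lost it without Fto -/- replicate 4, each of the other 13 lost it in 4 to 7 of the 8 fits without 1 array, and 0 changed sign. Slide row was uneven between the genotypes: row 1 held Fto -/- replicates 1, 2 and 3 and Fto +/+ replicate 1. Slide column was uneven too: column 1 held Fto -/- replicates 1 and 4, and column 4 held Fto +/+ replicates 1 and 4. Column was not fitted as a block. With slide row as a block 33 probes rose and 13 fell, and 6 of the 24 genes passed: Ptgds (1.99), Mttp (1.95), Rbfox1 (1.92), Begain (1.95), Kcnip4 (-1.6) and H2bc4 (-1.23). The other 18 had adjusted p values from 0.0568 to 0.171 in that fit, while their fitted log2 differences were 0.83 (Bcan) to 1.11 (Asb5) times those without the block. Within row 1 limma called 0 probes higher and 0 lower (1298 and 813 at an unadjusted p under 0.05), and within row 2 it called 1 and 0 (792 and 599). Without Fto -/- replicates 1, 2, 3 and 4 in turn, 73, 140, 62 and 55 probes were higher and 60, 119, 49 and 46 lower. Without Fto +/+ replicates 1, 2, 3 and 4 in turn, 91, 113, 87 and 499 were higher and 52, 76, 65 and 387 lower.

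Of the prostanoid synthesis and receptor genes Ptgds rose and 17 of 18 measured did not pass. Adjusted over the list alone, Ptgds rose and the thromboxane receptor gene Tbxa2r fell (-0.38 ± 0.08 SE, list-alone adjusted p = 0.0117). In the m6A machinery, the proteins that write, remove and read methyl groups on RNA adenosine, Fto fell and 18 of 19 did not pass; adjusted over the list alone, Igf2bp2, a reader gene, also rose (0.65 ± 0.13 SE, 0.0102). Of the genes neighbouring Fto, 0 of 6 measured passed in limma (2 at an unadjusted p under 0.05), and adjusted over the list alone 0 did. In nitric oxide, endothelin and angiotensin signalling 0 of 18 genes passed (9 at an unadjusted p under 0.05). When adjusted over the list alone, the angiotensin receptor gene Agtr1b (1.23 ± 0.27 SE, 0.0307) and the endothelin receptor gene Ednra (0.59 ± 0.16 SE, 0.0375) rose. The guanylate cyclase subunit gene Gucy1a1 fell (-0.38 ± 0.1 SE, 0.0375). Over all tested probes the limma adjusted p was 0.0694 for Agtr1b, 0.108 for Ednra and 0.111 for Gucy1a1. None of these 4 lists passed by camera (adjusted p of 0.198, 0.978, 0.99 and 0.99). By fry's mixed test, which asks whether genes of a list change in either direction and compares them with no other genes, the prostanoid and nitric oxide lists passed (adjusted p 2.41e-05 and 2.33e-05) and the neighbours did not (0.157). The m6A list, which holds the deleted gene, passed that test also without Fto (18 genes, adjusted p = 0.0017). Of all 25292 tested probes, 4806 had an unadjusted p under 0.05. At that level were 5 of 19 m6A genes, Fto among them, and 4 of 18 prostanoid genes. These shares lie near that of all probes, so passing the mixed test does not set the m6A and prostanoid lists apart from other genes.

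Genes of contractile smooth muscle were lower as a list (median log2 difference -0.28, camera adjusted p = 0.0124), with an adjusted p = 0.731 with an estimated correlation. Of 20 measured genes 2 fell and 18 did not pass: the tropomyosin genes Tpm1 (-0.65 ± 0.13 SE, adjusted p = 0.0463) and Tpm2 (-0.53 ± 0.1 SE, adjusted p = 0.0465). Adjusted over the list alone, 8 fell and 1, Des, rose (0.41 ± 0.12 SE, 0.0247). The other 4 Tpm1 probes differed by -0.2 to 0.1 and the other Tpm2 probe by -0.49, and 0 of these 5 passed. Tpm1 kept its call only without Fto +/+ replicate 4, and Tpm2 in 0 of the 8 fits without 1 array (-0.59 to -0.49); with slide row as a block they differed by -0.62 and -0.51 (adjusted p 0.185 and 0.186). Acta2 differed by 0.08 ± 0.1 and Myh11 by 0.07 ± 0.15 (SE, adjusted p 0.698 and 0.836). Acta2 differed by -0.01 with quantile normalisation and by -0.02 in the series table, and the fits without 1 array ran from 0.03 (Fto +/+ replicate 2) to 0.15 (Fto +/+ replicate 4) for Acta2 and from -0.01 to 0.2 (the same arrays) for Myh11. The list did not pass with slide row as a block (-0.21, adjusted p = 0.0558), without Fto -/- replicate 1 (-0.25, 0.0521) or without Fto +/+ replicate 4 (-0.2, 0.264); within rows 1 and 2 it was -0.15 (0.294) and -0.22 (0.0116). Nor did it pass with array weights (-0.23, 0.135) or with the T cell level as a covariate (-0.23, 0.173).

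Of the endothelial genes 0 of 21 passed (5 at an unadjusted p under 0.05), and 0 when adjusted over the list alone. In the collagen and elastic matrix, Col12a1 fell 1.59-fold (-0.67 ± 0.12 SE, adjusted p = 0.0382) and 25 of 26 did not pass. Col12a1 passed when adjusted over the list alone, where the fibronectin gene Fn1 (-0.45) also fell, and Col6a3 (0.32) and Postn (0.36) rose. Neither list passed (camera adjusted p 0.805 and 0.59). In the insulin-like growth factor and growth hormone axis, Igf2 rose 2.17-fold (1.12 ± 0.16 SE, adjusted p = 0.0192), measured above background in 2 of the Fto +/+ samples. Igfbp5 rose 1.67-fold (0.74 ± 0.12 SE, adjusted p = 0.0276) and Igfbp7 fell 1.75-fold (-0.8 ± 0.14 SE, adjusted p = 0.0383); both encode proteins that bind these growth factors or related ligands. The other 12 of 15 measured genes did not pass. With p adjusted over the list alone, 4 rose and 4 fell, with Igfbp3 and H19 (1.14) also higher and the growth hormone receptor gene Ghr (-0.63), its feedback inhibitor gene Socs2 (-0.88) and Igf1r (-0.49) also lower. Igfbp3 was not well above background on any Fto +/+ array and was at least 1.61-fold higher. A second Ghr probe (-0.72, adjusted p = 0.0246) and 1 of the other Socs2 probes (-1.08, adjusted p = 0.0165) passed over all probes. The list as a whole did not pass (camera adjusted p = 0.59). Col12a1, Igf2, Igfbp5 and Igfbp7 did not pass with slide row as a block (-0.68, 1.09, 0.76 and -0.81; adjusted p from 0.0988 to 0.146). Col12a1 and Igfbp7 kept their call only without Fto +/+ replicate 4. Igfbp5 lost it without Fto -/- replicates 1, 3 or 4 or Fto +/+ replicates 1, 2 or 3, and Igf2 without Fto -/- replicates 1, 3 or 4 or Fto +/+ replicate 1. Over all 8 fits without 1 array, Igfbp5 ran from 0.68 to 0.83 and Igf2 from 1 to 1.27.

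Brown adipocyte genes were higher as a list, with a median log2 difference of 0.71 and a camera adjusted p of 1.35e-05 (adjusted p = 0.731 with an estimated correlation). Of 19 measured genes 0 passed singly in limma (13 at an unadjusted p under 0.05). The count adjusted over the list alone was 12 higher and 1 lower. Cidea differed by 1.88 ± 0.47 (SE, adjusted p = 0.0883), Fabp3 by 1.19 ± 0.3 (adjusted p = 0.0923) and the uncoupling protein gene Ucp1, which lets brown fat produce heat, by 2.9 ± 0.94 (adjusted p = 0.153). White adipocyte genes were higher as a list (median 0.75, camera adjusted p = 0.00149; adjusted p = 0.731 with an estimated correlation), with 0 of 17 passing (3 at an unadjusted p under 0.05), and 0 adjusted over the list alone; Dgat2 differed by 1.5 ± 0.37, Trarg1, measured in 2 of the Fto +/+ samples, by 0.97 ± 0.39 and the adiponectin gene Adipoq by 0.86 ± 0.65 (SE). Adipoq differed by 0.31 without Fto +/+ replicate 2, 0.49 without Fto -/- replicate 3 and 1.29 without Fto +/+ replicate 3. Fatty acid and triglyceride synthesis (median 0.41, adjusted p = 0.0013; 0 of 18), fatty acid oxidation (median 0.34, 0.000505; 0 of 19) and the respiratory chain (median 0.2, 0.000602; 0 of 27) were also higher as lists, with 6, 7 and 1 genes at an unadjusted p under 0.05. With an estimated correlation each of these 3 lists had an adjusted p = 0.731. The respiratory chain level ran from -0.25 to 0.36 in Fto -/- and from -0.13 to -0.02 in Fto +/+ arrays, so the genotypes overlapped. Of the synthesis list, adjusted over the list alone, Agpat2 (1.01), Elovl6 (1.24), Thrsp (1.26) and Acacb (0.83) rose. Cpt2 differed by 0.61, Sdhb by 0.41 and Ndufv1 by 0.29, with adjusted p from 0.13 to 0.275, and 0 genes of these lists passed adjusted over the list alone. With slide row as a block these 5 lists passed with medians of 1.08, 0.96, 0.42, 0.45 and 0.26 (brown, white, synthesis, oxidation, respiratory chain). Within row 1 the medians were 1.17, 0.88, 0.64, 0.4 and 0.19 and within row 2 0.91, 0.9, 0.21, 0.54 and 0.32. Each row sets 1 array of one genotype against 3 of the other, so these values are no independent support. Without Fto -/- replicate 3 the white adipocyte median was 0.49 (camera adjusted p = 0.0211) and the respiratory chain median 0.11 (0.0251), and without Fto +/+ replicate 2 the white adipocyte median was 0.37 (0.0459).

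The white adipocyte level differed from array to array within each genotype, from -0.19 to 1.01 in Fto -/- and from -1.11 to 0.53 in Fto +/+ samples. With that level as a covariate, chosen after seeing the data, brown adipocyte genes had a median of 0.78 (camera adjusted p = 7.24e-05; adjusted p = 0.769 with an estimated correlation), while fatty acid oxidation, the respiratory chain, and the fibroblast and macrophage lists had camera adjusted p values of 0.0569, 0.19, 0.0895 and 0.0895. The medians of oxidation and respiratory chain were 0.1 and 0.06 there, and that of fatty acid and triglyceride synthesis 0.26 (camera adjusted p = 0.00848). In that fit 40 probes rose and 14 fell.

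T cell genes were higher as a list (median 1.21, camera adjusted p = 0.00143; adjusted p = 0.731 with an estimated correlation), and 0 of 15 passed (1 at an unadjusted p under 0.05), and 0 adjusted over the list alone. Over probes well above background on all 8 arrays alone the list did not pass (0.13, camera adjusted p = 0.274). Cd3g differed by 2.54 ± 0.89 (SE, adjusted p = 0.182), measured in 1 of the Fto +/+ samples. Rag1, which developing lymphocytes use to rearrange receptor genes, was well above background on 3 Fto -/- arrays and 1 Fto +/+ array (1.79 ± 1.23 SE, adjusted p = 0.457; 2.78 without Fto -/- replicate 2 and 2.85 without Fto +/+ replicate 2). Inflammation and leukocyte adhesion (median 0.66, camera adjusted p = 0.00545; 0 of 12), cell cycle (0.44, 0.00322; 0 of 15), fibroblast and adventitia (0.22, 0.0124; 0 of 16) and macrophage and myeloid genes (0.37, 0.0308; 0 of 21) were higher as lists. With an estimated correlation their adjusted p was 0.731, and 0.749 for macrophage and myeloid genes. At an unadjusted p under 0.05 limma had 3, 7, 2 and 0 genes of these lists. Of the inflammation list, adjusted over the list alone, the chemokine genes Ccl11 (1.16) and Cxcl12 (1.22) rose and 0 genes of the other 3 lists did. A second Cxcl12 probe differed by 0.2 and did not pass. Ccna2 (0.69), Plk1 (0.55), Fbln1 (0.5), Lum (0.93), S100a9 (-1.34, measured in 3 of the Fto -/- samples) and Itgam (0.45) did not pass. Without Fto +/+ replicate 4, Lum differed by 0.59 and Itgam by 0.71, without Fto +/+ replicate 2 Itgam by 0.3, and without Fto -/- replicate 2 S100a9 by -0.62. With slide row as a block the T cell, inflammation and cell cycle lists passed (1.8, 0.61 and 0.45). Within row 1 they were 2.11, 0.4 and 0.38 and within row 2 1.33, 0.84 and 0.43, with 1 array against 3 in each row. The T cell median was 1.83 without Fto -/- replicate 2 and 1.94 without Fto +/+ replicate 2, and the inflammation median 0.41 without Fto +/+ replicate 2. The fibroblast and macrophage lists did not pass with slide row as a block (0.18 and 0.33, adjusted p 0.0558 and 0.0838), nor without Fto -/- replicate 1 (0.14 and 0.2) or Fto +/+ replicate 4 (0.03 and 0.02). Within row 1 they were -0.05 and -0.01, and within row 2 0.41 and 0.63. With array weights they were 0.09 and 0.2 (adjusted p 0.165 and 0.135). The macrophage list also did not pass without Fto -/- replicate 4 (0.3, adjusted p = 0.0708), and the inflammation list not without Fto -/- replicate 1 (0.4, 0.0521). Without Fto +/+ replicate 3 the fibroblast and macrophage medians were 0.37 and 0.57, and without Fto -/- replicate 2 the macrophage median was 0.59.

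Without the 4 arrays on which Rag1 was well above background, chosen after seeing the data, limma called 0 probes higher and 0 lower, with 1299 and 995 at an unadjusted p under 0.05. That fit holds 1 Fto -/- array, assumed to vary like the others. Of the lists called higher, fatty acid and triglyceride synthesis had a median of 0.54 there and the respiratory chain one of -0.16, both resting on that 1 array. White adipocyte (-0.22), fibroblast (-0.02) and macrophage genes (-0.2) had medians below 0, and brown adipocyte (0.35), T cell (0.15), cell cycle (0.12) and inflammation genes (0.03) did not pass. The contractile list did not pass either (-0.13, camera adjusted p = 0.391). With the T cell level as a covariate 52 probes rose and 29 fell, and the T cell, cell cycle, macrophage, respiratory chain and contractile lists did not pass. For the T cell list this was fixed in advance, because the covariate is its own level.

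In the interferon response Ifit2 fell (-0.58 ± 0.11 SE, adjusted p = 0.0465) and 13 of 14 did not pass; adjusted over the list alone Cxcl9, not well above background on any Fto +/+ array, also rose (at least 1.03-fold). Ifit2 lost its call with slide row as a block (-0.55, adjusted p = 0.185). Of the 8 fits without 1 array, which ran from -0.65 to -0.52, it kept the call only without Fto -/- replicate 2 or Fto +/+ replicate 4. That list did not pass (camera adjusted p = 0.568).

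**Figure D2:**
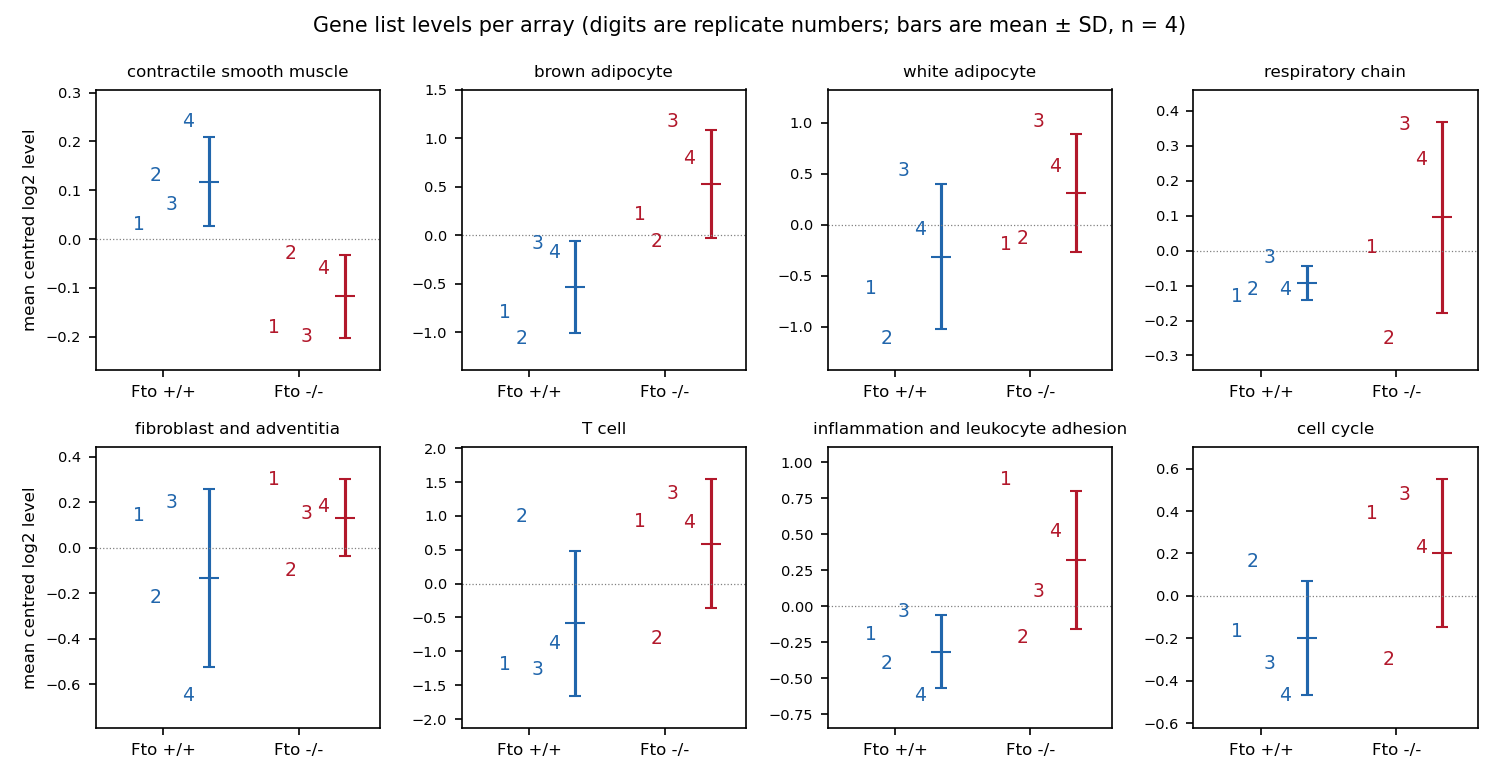
Mean centred log2 level of 8 gene lists (y axes) in each array by genotype (x axes); digits are replicate numbers and bars are the mean ± SD with n = 4. T cell levels are 0.91 to 1.33 in Fto -/- replicates 1, 3 and 4 and 0.99 in Fto +/+ replicate 2, and brown adipocyte levels run from -1.06 to 1.17.

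In all, camera called 10 lists higher and 1 lower of 27, while 0 passed with an estimated correlation and 0 by fry's directional test, with 0 and 3 at an unadjusted p under 0.05. For the lists called, the estimated correlation ran from 0.21 to 0.82, above the preset 0.01, which treats genes as nearly independent. An exact two-sided permutation test of the list level over arrays, unadjusted, gave p = 0.0286 for the contractile and brown adipocyte lists. For the other lists called, that p ran from 0.0571 (synthesis) to 0.486 (macrophage). By fry's mixed test 7 lists passed, with or without Fto in the m6A list: besides the 3 named above, the matrix (adjusted p = 2.46e-07), contractile (2.95e-05), insulin-like growth factor (0.00057) and brown adipocyte lists (0.0347). The lists of cholesterol synthesis, skeletal muscle, cardiac muscle, erythroid cells, Schwann cells and nerve, thymus and epithelium, circadian clock, and immediate early and heat shock genes did not pass, with camera adjusted p of 0.915, 0.129, 0.59, 0.805, 0.59, 0.393, 0.179 and 0.381, and 0 of their genes passed in limma, or did so adjusted over the list alone. At an unadjusted p under 0.05 there were 2 skeletal muscle genes, 1 Schwann cell gene and 0 of the other 6 lists. B cell genes (4 measured, 0 passing) and Y-linked genes with Xist (1 measured) were under the minimum for a list test; Xist differed by 0.61 ± 0.15 (SE, adjusted p = 0.0901). The median and camera's direction had opposite signs for the m6A (-0.05, mean -0.12), nitric oxide (-0.18, mean 0.05), matrix (-0.06, mean 0.02) and cholesterol (-0.03, mean -0.03) lists.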

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

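The tests of tissue sources, of the noise floor and of sex were chosen only after the results were seen; the count over other splits was planned. Of 240 groups of 4 arrays examined, 15 held an array far from the other 3, and chance gives about 1 in 20. In Fto +/+ samples, Aqp5 stood at -3.98 in replicate 3 (others -5.17 to -5.01), Ptgds at -3.56 in replicate 4 (-2.82 to -2.74), Rnf39 at -2.78 in replicate 1 (-2.23 to -2.2) and Fn1 at 7.34 in replicate 3 (7.54 to 7.57). In Fto +/+ replicate 2, Cd3g stood at -1.57 (-5.5 to -5.11), Rag1 at -1.24 (-5.62 to -5.37) and Plk1 at -0.86 (-1.53 to -1.49). In Fto +/+ replicate 3 the respiratory chain level was -0.02 (-0.13 to -0.11) and 1 Uty probe stood at -0.88 (-5.47 to -5.26). In Fto -/- samples, Tpm1 stood at 4.19 and Fn1 at 6.81 in replicate 3 (4.6 to 4.66 and 7.12 to 7.15), and Actg1 at 8.77 in replicate 2 (8.64 to 8.66). In Fto -/- replicate 1, Fbln1 stood at 5.07 (4.79 to 4.83), Elovl6 at 0.52 (1.61 to 1.73) and the circadian clock level at -0.34 (0.26 to 0.34).

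Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave as many as 419 probes past the threshold. That rank is the strongest result that 35 splits can give, so it argues against chance but cannot exclude it. It does not tell genotype from other differences between the groups, such as slide row, slide column or tissue carried over. The highest other split gave 42 and set Fto -/- replicates 1, 3 and 4 with Fto +/+ replicate 2, the arrays on which Rag1 was well above background.

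The median level of 13 thymocyte genes, a list written after the arrays were examined, ran over 3.41 log2 units: 1.2, -1.17, 1.9 and 0.84 in Fto -/- replicates 1 to 4 and -1.51, 1.47, -1.39 and -1.21 in Fto +/+ replicates 1 to 4. Dntt stood at 1.22, -2.94, 1.79 and 0.79, and at -2.25, 1.61, -3.45 and -2.55, in the same order. The T cell list holds 2 of these genes and the thymus and epithelium list 3, and 2 were well above background on all 8 arrays. The median of 11 B cell genes ran over 0.64, but 3 to 6 of the 11 were well above background per array, so blood or lymph node stays open: Cd79b stood at -1.74, -3.36, -2.31 and -1.04, and at -3.16, -2.9, -3.06 and -2.88, and the erythroid level at 1.09, -0.66, -0.14 and -0.21, and at -0.8, 0.61, -0.04 and 0.14. Thymus tissue carried over with some aortas remains a candidate explanation, and a genotype effect on it was not tested. The cardiac muscle level also varied between arrays. It was -0.54, 0.63, -1.87 and 1.9 in Fto -/- replicates 1 to 4, and -0.79, 0.95, 0.23 and -0.5 in Fto +/+ replicates 1 to 4. The cause of that spread was not tested.

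Brown adipocyte genes were higher as a list by camera, but with an adjusted p = 0.731 with an estimated correlation and 0.37 by fry, and without the 4 arrays on which Rag1 was well above background the median was 0.35 and did not pass (0.101). The 16 brown adipocyte genes well above background on all 8 arrays had a median log2 difference of 0.92, which argues against the noise floor. The brown level minus the white level was 0.22 ± 0.14 in Fto -/- and -0.22 ± 0.28 in Fto +/+ samples (SD, n = 4; exact two-sided permutation p = 0.0286), but the nearest arrays, Fto -/- replicate 2 and Fto +/+ replicate 2, stood at 0.07 and 0.06, a gap under the SD of either genotype. With the white level as a covariate the oxidation and respiratory chain medians, of lists that share 0 genes with the white list, went from 0.34 to 0.1 and from 0.2 to 0.06. The brown median was 0.78 there, above the SD of its members (0.57). Camera gave it an adjusted p of 7.24e-05, and of 0.769 with an estimated correlation. The criterion of a median above that SD was set after the median was known, and an SD over genes does not measure the spread between arrays. A fat share that the white level tracks therefore stays open as the whole cause. A larger share of brown fat in the Fto -/- pieces and a genotype effect within fat cells were not tested apart, and both remain candidate explanations.

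The labels give male for all samples, while the sex-linked probes read otherwise. Both Xist probes were well above background on 8 of 8 arrays, which argues against male animals with failed Y-linked probes. In 0 of 40 pairs of a Y-linked gene and an array was every probe of the gene well above background. A candidate explanation is that the 8 aortas came from female mice, a hypothesis formed on these same data.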

How the results depend on the processing

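The normexp fit, the fits without the 4 arrays with Rag1, with the T cell or white adipocyte level as a covariate, and within slide rows were chosen after seeing the data. The planned normexp on the mean spot signal was not run, because the files used here hold the median spot signal, which took its place; slide or scan date as a block was not run, because all arrays share both. The Fto difference kept its direction throughout, from -3.33 to -1.96, and its call except without the 4 arrays (-2.66) and in row 1 (-3.02) or row 2 (-3.33) alone, which leave few arrays. Background correction, quantile or median scaling, the series table, outlier spots, probes above background on all arrays and trend with robust eBayes kept both probe counts within 1.5 times of 213 and 206.

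Probe counts higher and lower were 61 and 35 with no filter on dim probes (more probes tested), 33 and 13 with slide row as a block, 777 and 847 with array weights, and 106 and 48 with a fitted log2 difference of at least 1. They were 0 and 0 without the 4 arrays, 52 and 29 with the T cell covariate, 40 and 14 with the white adipocyte covariate, 0 and 0 in row 1, and 1 and 0 in row 2. Leaving out 1 array gave 55 to 499 higher and 46 to 387 lower: 73 and 60, 140 and 119, 62 and 49, and 55 and 46 without Fto -/- replicates 1 to 4, and 91 and 52, 113 and 76, 87 and 65, and 499 and 387 without Fto +/+ replicates 1 to 4. Apart from the fewer arrays, more probes or stricter threshold that some settings impose, the cause was not tested.

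The replicate numbers did not pair the samples: same-numbered deviations correlated at 0.15, -0.02, -0.02 and -0.04, and not every array correlated best with its own number. With the replicate block 90 probes were higher and 42 lower, of which 60 and 34 were among those called without it, and 10 lists were higher and 2 lower.

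Of 27 lists, 10 were higher and 1 lower. An estimated correlation gave 0 and 0, and fry's directional test 0 and 0. With the T cell covariate 6 were higher and 0 lower, and with the white adipocyte covariate 5 and 2. Without the 4 arrays only 1 Fto -/- array was left, so list calls are not counted for that fit. Slide row as a block gave 0 lower, array weights 0 lower and row 2 alone 3 lower. Leaving out 1 array gave 8 to 10 higher and 0 to 2 lower. The cause was not tested. Without the 4 arrays the median difference changed sign for fibroblasts (-0.02), white adipocytes (-0.22), respiratory chain (-0.16) and macrophages (-0.2), and was 0 for fatty acid oxidation. Sdhb (-0.06), Ndufv1 (-0.01), Adipoq (-0.6) and Rag1 (-0.12) also changed sign there. So did Rag1 with the T cell covariate (-0.63), white adipocytes (-0.06) and Adipoq (-0.18) with the white adipocyte covariate, fibroblasts (-0.05) and macrophages (-0.01) in row 1, and S100a9 in row 2 (0.15). The white adipocyte list loses its difference by construction when its own level is the covariate. Acta2 did with quantile normalisation (-0.01) and in the series table (-0.02), and Myh11 without Fto +/+ replicate 2 (-0.01; up to 0.2 without Fto +/+ replicate 4). Of 971 differences of 41 named genes past the threshold, over all settings, 534 kept their call, 437 lost it and 0 changed sign. Dim probes limit the folds: 48 probes past the threshold were not well above background on any array of 1 genotype.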

Other observations

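The test of neighbouring genes was chosen only after the results were seen; those of the cilia and SRF lists were set out before their values were seen. The genes named here were chosen after their values were seen. Cck, which encodes the peptide hormone cholecystokinin, rose with little spread (log2 difference 1.71 ± 0.1 SE, adjusted p = 0.000828), and so did Cyp7b1, an oxysterol hydroxylase gene (1.4 ± 0.1 SE, adjusted p = 0.00109). Both kept their call with slide row as a block (1.68 and 1.38) and without any 1 of the 8 arrays. All 3 probes of the chemokine gene Ccl19 rose, by 1.2, 1.18 and 1.19, and both of Hopx, by 1.45 and 1.04; with slide row as a block Ccl19 (1.12) and Hopx (1.29) did not pass (adjusted p = 0.0613 each). Both probes of Srf, a transcription factor gene of actin and muscle genes, fell (-0.54 and -0.69); its brighter probe lost its call with slide row as a block (-0.52) and kept it only without Fto -/- replicate 2 or Fto +/+ replicate 4. Of 5 Actg1 probes 2 fell, while the brightest differed by -0.09.

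Of the probes past the threshold, 63 carried a genomic region as their name, from 46 regions. On chromosome 17 (mm9) 3 probes of the region from 32044823 to 32045974 rose by 2.2 to 2.5 on the log2 scale. On chromosome 6, 3 probes from 129151512 to 129208737 rose by 2.29 to 2.38, and on chromosome 4, 3 from 149445201 to 149445902 by 1.28 to 1.92. Their genes are not named in the sources used here.

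Srf, Actg1, Tpm1 and Tpm2 were among the genes that fell. Lower expression of SRF targets and the actin cytoskeleton as a group was therefore a hypothesis. The 27 measured genes of such a list, written without the genes seen, had a median log2 difference of -0.17, with 22 below 0. The camera p was 0.00292, and 0.0441 with an estimated correlation. The median missed the bound of -0.2 set beforehand, so this remains open. The list held no genes of the contractile list, of which 6 were above 0 and 14 below (median -0.28). Among those, Acta2 differed by 0.08, Tagln by 0.1, Myh11 by 0.07 and Cnn1 by -0.32.

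Cilia genes seen among those that rose led to a like test. The 8 measured genes of motile cilia had a median log2 difference of 0.03, with 5 above 0 and 3 below. That was under the bound of 0.1 set beforehand against a cilia program, but by less than the members' SD of 0.34, so it decides nothing.

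DNA carried along with the deleted gene from another strain may alter genes beside it. Among the 200 tested genes nearest to Fto, 2.5% passed the threshold against 1.78% elsewhere (Fisher's exact test, two-sided p = 0.412), and the 5 were Ces2e (0.98, measured in 1 of the Fto +/+ samples), Setd6 (-0.72), Ces2g (0.69), Slc38a7 (-0.52) and Tbc1d9 (-0.99). With slide row as a block 0 of the 5 passed in limma (adjusted p from 0.0974 to 0.185), with differences of 0.92, -0.73, 0.63, -0.57 and -0.9. The numbers are too few to decide.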
